A study of Drosophila melanogaster with 24 samples.

How the data were processed

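The series holds 24 RNA-seq libraries of Drosophila melanogaster in 7 groups. Per the labels, 3 groups of 4 libraries come from the midgut and carry a temperature-sensitive esg driver, which is active in intestinal stem cells and their enteroblast daughters. They are lacZ flies at 10 days, lacZ flies at 30 days, and flies with an RNAi knockdown of Adar at 10 days. The other 4 groups hold 3 libraries each: an overexpression of the E374A form of ADAR with its control, and a knockdown of Zn72d with its control. The tissue label of these 12 libraries is whole organism, whereas the extract protocol of all 24 libraries describes midgut stem cells sorted by flow cytometry. The protocol names paired-end sequencing on a NovaSeq instrument. Groups were taken from the sample titles and descriptions. Nothing in the labels says that replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

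Per the submitters' processing notes, reads were aligned with STAR 2.7.1a and quantified with StringTie, for which no version is given, on genome build dm6. The annotation release and the settings, strand included, are not given in the sources used here. Overlapping or antisense genes and near-identical copies are therefore reported as uncertain. The authors deposited 1 gene abundance table per library, with a read coverage, an FPKM and a TPM value for each gene. Per the file headers, the TPM column holds transcript abundance scaled to a fixed total, and the FPKM column fragments scaled by gene length and depth. In 11 libraries the deposited TPM sum to 1000000 over 17830 FlyBase genes and 6052 other features, of which 5416 are transposon insertions. The other 13 libraries, which are the 12 midgut libraries and the library labelled E374A control 3, came as tables of loci assembled by StringTie. In these the deposited TPM column is a signal that sums to more than 1000000: the assembled loci sum to 1000000, and annotated genes carry between 881199 and 987040 on top. The values of the annotated genes were used as deposited. The deposited coverage, the mean read depth per base, is a signal in the 11 tables of the first format. In the other 13 tables the coverage column holds a few values slightly below 0, so its deposited unit was recorded as other. Coverage served only to compare libraries with each other and to estimate aligned bases as coverage over FPKM. These estimates ran from 3.397 to 6.7 gigabases in the 13 libraries and from 5.687 to 7.742 in the 11. Read counts per gene were not used here, so no interval for counting error is given. Genes were matched by current symbol: 17751 of 17830 FlyBase identifiers, and 16293 of 17137 symbols of the assembled tables, had a match.

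Gene tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend and robust variances, through statmod 1.5.0) on log2(TPM + 1). They covered genes with a mean TPM of at least 1 over the libraries in the fit. The test was two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The 3 midgut groups were fitted together and the other comparisons alone, without a block for the replicate number. Errors of log2 fold changes are standard errors, and errors of TPM are standard deviations. A total of 39 gene lists for cell types, pathways, stress and the machinery of transcription and translation were fixed, with the genes on chromosome X as a further list. The test was camera with a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison, for lists with at least 5 tested members, which were 36 in each comparison, chromosome X included. Camera with an estimated correlation and fry stood beside it. Targeted genes were also tested by an exact two-sided permutation of TPM, which with 3 against 3 libraries cannot go below 0.1. Overlaps used one-sided Fisher tests, with 100 simulations of unchanged groups against shared controls. Files were read and figures drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

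The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took Adar and Zn72d. It took per comparison the 10 called genes with the largest and the 10 with the smallest log2 fold change, with a mean TPM of at least 5 in the higher group and a symbol other than a bare CG or CR number, an antisense RNA or an unnamed locus. It took up to 2 called members per list and direction, or up to 2 abundant members where none was called, and up to 10 genes per direction called in at least 2 comparisons. The text names a part of these genes. esg, neighbours of a named gene and genes named for a count of 5 or fewer were chosen after their values were seen. The unit expected beforehand for a count test was not present, so no count test was run.

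The pipeline was tested on simulated data with 100 genes changed at each size. At a log2 change of 1 it recovered 37% in the age comparison (8717 genes tested), 31% in the Adar comparison (8717 genes), 0% in the E374A comparison (8270 genes) and 69% in the Zn72d comparison (8468 genes). At a log2 change of 2 it recovered 82%, 80%, 0% and 96% in the same order, with 6, 4, 0 and 9 false calls. Without the library labelled E374A control 3 the E374A values were 44% and 96%, with 14 false calls among 7920 genes. A shifted list was recovered in each simulation, and 0 of 20 unshifted lists were called by camera. The simulated genes varied independently of each other, so this cannot show how camera behaves on lists of correlated genes.

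Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, FPKM, a replicate block, limma array weights, each library left out, a fit on the compared groups only, a joint fit of the E374A and Zn72d libraries, and camera with an estimated correlation. Rescaling the annotated genes of each library to 1000000, and averaging the 10-day lacZ libraries 3 and 4 as 1, were chosen after seeing the data. Counting the shared libraries once in the joint fit, by averaging each matching pair, also followed from a match seen in the data.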

Results

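RNA was sequenced from Drosophila to ask how gene expression differs in intestinal stem cells of young and aged flies, and after changing the RNA editing enzyme ADAR or the zinc-finger protein Zn72D. ADAR deaminates adenosines in double-stranded RNA. Zn72D is an RNA-binding protein known for roles in editing and in dosage compensation. The midgut set held lacZ flies at 10 days, lacZ flies at 30 days and Adar knockdown flies at 10 days, with 4 libraries each. The second set held an overexpression of the E374A form of ADAR, a knockdown of Zn72d and a control for each, with 3 libraries per group. Between 8070 and 8702 genes lay above 1 TPM in the 13 libraries deposited as assembled tables, and between 8111 and 8677 in the other 11.

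The targeted genes were examined first. Adar (FBgn0026086, dm6 chromosome X, 1773725 to 1788065) fell in the Adar knockdown libraries to 14.6 ± 6.80 TPM (SD, n = 4), or 38.8% of the 37.7 ± 6.76 TPM (n = 4) of the 10-day lacZ libraries. Its log2 fold change was −1.40 ± 0.31 by limma (adjusted p = 0.0124), and −1.02 after median-ratio scaling (adjusted p = 0.0477). With quantile normalization the call was lost. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow. The 4 knockdown libraries had 16.05, 11.2, 23.5 and 7.78 TPM, and the 10-day lacZ libraries 29.2, 37.5, 45.7 and 38.6 TPM. The 30-day lacZ libraries had 38.1, 19.5, 21.3 and 23.0 TPM. Zn72D (FBgn0263603, chromosome 3L, 16106594 to 16112626) did not pass the test in the Zn72d knockdown. Its values were 10.6, 17.9 and 15.999 TPM in the knockdown libraries and 18.6, 18.1 and 16.9 TPM in the controls (log2 fold change −0.28 ± 0.22, adjusted p = 0.471 by limma, exact permutation p = 0.2).

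In the E374A set the values of Adar ran against the titles. The libraries labelled control 1 and 2 had 879 and 801 TPM of Adar, the library labelled control 3 had 31.5 TPM, and the libraries labelled overexpression had 17.2, 14.5 and 15.8 TPM. The log2 fold change of labelled overexpression against labelled control was −4.08 ± 1.31 over the 6 libraries (adjusted p = 0.583 by limma). Without the library labelled control 3 it was −5.64 ± 0.18 (adjusted p = 2.67e-07). The deposited names of the 6 files of this set run opposite to their titles in 6 of 6. Every direction given for this set follows the titles. These Adar values, and the match of the libraries labelled overexpression to the Zn72d controls given below, argue against the titles. If read by the file names instead, every direction turns.

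**Figure D1:**
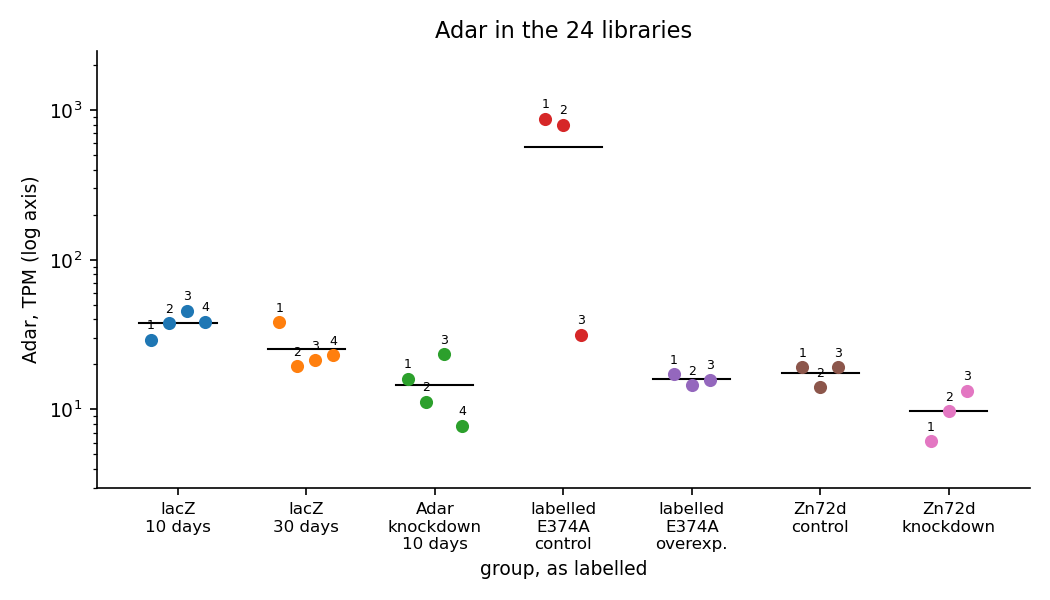
TPM of Adar in each of the 24 libraries (log axis), grouped as labelled; points are libraries with their replicate number and lines are group means. The libraries labelled E374A control 1 and 2 lie at 879 and 801 TPM, and the 4 Adar knockdown libraries between 7.78 and 23.5 TPM.

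Libraries were compared before they were averaged. Each library labelled E374A overexpression matched the Zn72d control of the same number for most genes. Coverage was equal within 0.1% for 82.8% to 83.1% of genes in these 3 pairs, and for at most 0.432% in any other pair of libraries deposited in the same format. The deposited values were not identical: 68 to 86 genes per pair differed by over 1 on the log2 scale, such as the overlapping genes anox and SLIRP1, at 60.4 against 2.68 and 15.8 against 74.2 TPM in pair 1. The E374A and Zn72d comparisons therefore share 3 libraries and are not independent. The library labelled E374A control 3 resembled the midgut set: its Spearman correlation across 6803 genes was 0.965 with 10-day lacZ library 4 and averaged 0.326 with its own group. It had 323 TPM of esg, the transcription factor that marks intestinal stem cells and enteroblasts, against 10.1 and 20.6 TPM in labelled controls 1 and 2. Digestive enzymes summed to 363 TPM in it, and to 241109 and 177654 TPM in labelled controls 1 and 2. Over the Zn72d and labelled overexpression libraries, 186994 to 256676 TPM came from the same 41 digestive enzymes, and Mhc, the muscle myosin heavy chain, had 67.0 to 176 TPM. In the midgut set the digestive enzymes summed to between 84.6 and 2036 TPM, Mhc stayed at or under 1.33 TPM and esg ran from 189 to 802 TPM.

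Library 1 of the 10-day lacZ group stood apart, with a mean correlation of 0.890 to its group. It had 90.9 TPM of the yolk protein gene Yp1 and 10.4 TPM of roX1, a non-coding RNA of male dosage compensation, against at most 0.900 and 0.0815 TPM in the other 3 libraries. Library 1 of the 30-day group also had 10.5 TPM of roX1. The 10-day lacZ libraries 3 and 4 were the most alike pair of the midgut set (correlation 0.993), with equal coverage for 0.432% of genes. Equal coverage detects only the same reads, so whether the pair comes from the same RNA was not tested.

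The median log2 fold change over all tested genes was below 0 in each comparison: −0.32 with age, −0.39 with Adar knockdown, −0.17 with Zn72d knockdown and −0.36 for labelled E374A overexpression. The deposited TPM of annotated genes summed to 963356 to 984051 in the 10-day lacZ libraries. They summed to 935996 to 950892 at 30 days and 881199 to 955176 on Adar knockdown, so this scale differs between the groups. Rescaling to 1000000 moved the median of chromosome X genes from −0.36 to −0.31 with age and from −0.42 to −0.32 on Adar knockdown. Directions of gene groups are given relative to the medians over all tested genes, and counts under median-ratio scaling stand beside those on TPM as deposited.

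The first comparison asked how sorted midgut cells of 30-day lacZ flies differ from those of 10-day flies. Some glutathione S-transferase, cytochrome P450 and gut hormone genes were higher at 30 days, and some cell cycle and splicing genes were lower. GstD10, a glutathione S-transferase, rose from 6.40 ± 2.65 to 63.3 ± 24.4 TPM (SD, n = 4 each; log2 fold change 3.10 ± 0.38, adjusted p = 0.00121). Ssk, a membrane protein of the smooth septate junctions of enterocytes, rose from 113 ± 12.7 to 386 ± 96.5 TPM (log2 fold change 1.73 ± 0.36, adjusted p = 0.0089). mira, whose product Miranda is segregated during asymmetric division, fell from 435 ± 73.5 to 138 ± 18.9 TPM (log2 fold change −1.64 ± 0.29, −1.32 relative to the median gene, adjusted p = 0.0055). Of 8717 genes tested, 377 were higher and 1359 lower, and after median-ratio scaling 506 were higher and 277 lower, of which 361 and 277 were called in that direction under both.

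Detoxification genes were among those higher with age. Of 50 tested genes for glutathione S-transferases and antioxidant defence, 15 were higher and 4 lower, and 19 and 4 adjusted over the list alone. The list was higher by camera (adjusted p = 7.94e-10; adjusted p = 0.056 with an estimated correlation). GstD5 rose from 44.4 ± 37.9 to 244 ± 117 TPM, and GstE8 by a log2 fold change of 2.65 ± 0.58. Of 44 cytochrome P450 genes 12 were higher and 1 lower, with 13 and 2 adjusted over the list alone (camera adjusted p = 1.12e-08; adjusted p = 0.176 with an estimated correlation). Cyp6a19 rose from 2.58 ± 1.21 to 22.2 ± 6.61 TPM and Cyp28a5 by a log2 fold change of 2.36 ± 0.58. The UDP-glycosyltransferase Ugt37A3 showed the largest named increase, from 2.91 ± 1.91 to 94.0 ± 61.9 TPM (log2 fold change 4.15 ± 0.88, adjusted p = 0.0102).

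Some markers of differentiated gut cells were also higher at 30 days. Among 20 enteroendocrine markers 4 were higher and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 2.49e-06; adjusted p = 0.498 with an estimated correlation). The gut peptide genes Mip and CCHa2 rose by log2 fold changes of 1.79 ± 0.41 and 1.87 ± 0.62 (adjusted p = 0.0126 and 0.0497). Of 11 genes of enterocyte identity and brush border 4 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 1.72e-05; adjusted p = 0.176 with an estimated correlation). mesh, a partner of Ssk at the junction, rose from 19.4 ± 3.01 to 67.8 ± 29.9 TPM, and Mur29B by a log2 fold change of 2.06 ± 0.58. The 16 septate junction genes, which share Ssk and mesh with the identity list, had 5 higher and 0 lower members, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.00699; adjusted p = 0.498 with an estimated correlation). Digestive enzymes had 2 higher and 0 lower of 32, and 0 adjusted over the list alone (camera adjusted p = 7.62e-08; adjusted p = 0.498 with an estimated correlation). Both were maltases, Mal-A1 and Mal-A8, and the maltase Mal-A4 rose from 2.85 ± 1.54 to 25.4 ± 9.24 TPM. Of 6 neuron markers 3 were higher, also adjusted over the list alone (camera adjusted p = 0.00179; adjusted p = 0.176 with an estimated correlation). Among them were brp, an active zone protein, and the microtubule-associated futsch, with log2 fold changes of 0.94 ± 0.29 and 1.08 ± 0.31. The enteroendocrine markers summed to between 1458 and 2457 TPM in the 30-day libraries, to between 669 and 725 TPM in the 10-day libraries 2 to 4, and to 3203 TPM in 10-day library 1.

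Some genes of proliferation and RNA handling were lower at 30 days. Of 40 cell cycle genes 0 were higher and 15 lower, with 24 lower adjusted over the list alone and 5 lower after median-ratio scaling (camera adjusted p = 0.000216; adjusted p = 0.585 with an estimated correlation). The median of the list lay −0.69 from that of all genes. pim, the fly securin, fell from 13.7 ± 6.85 to 3.28 ± 2.43 TPM (log2 fold change −1.85 ± 0.41), and the cyclin gene CycB3 by a log2 fold change of −1.67 ± 0.48, which did not pass after median-ratio scaling (adjusted p = 0.0769). Splicing genes had 0 higher and 12 lower of 33, with 18 lower adjusted over the list alone and 4 lower after median-ratio scaling (camera adjusted p = 0.000216; adjusted p = 0.498 with an estimated correlation). The splicing repressor Rsf1 fell from 89.5 ± 19.0 to 31.8 ± 3.56 TPM. Of 17 genes for RNA editing and its known regulators 8 were lower and 0 higher, with 9 lower adjusted over the list alone and 2 lower after median-ratio scaling (camera adjusted p = 0.00414; adjusted p = 0.498 with an estimated correlation). These included the DEAD-box helicase gene bel and the SR protein gene x16, with log2 fold changes of −1.07 ± 0.21 and −1.14 ± 0.22. Adar itself did not pass (25.5 ± 8.54 against 37.7 ± 6.76 TPM, log2 fold change −0.58 ± 0.31, adjusted p = 0.175).

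Of 19 stem cell and enteroblast markers, 1 was higher and 3 were lower with age, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.555). The lower ones included mira and the Notch target E(spl)m3-HLH (log2 fold change −1.31 ± 0.33), and the higher one was dila, a centrosomal protein gene, from 1.50 ± 0.61 to 10.1 ± 3.61 TPM. Mitochondrial ribosomal protein genes had 13 of 73 lower and 0 higher, with 12 adjusted over the list alone and 1 after median-ratio scaling (camera adjusted p = 0.00685; adjusted p = 0.88 with an estimated correlation). Of 86 cytoplasmic ribosomal protein genes 5 were higher and 1 lower, with 3 and 0 adjusted over the list alone and 19 and 0 after median-ratio scaling (camera adjusted p = 0.000101; adjusted p = 0.588 with an estimated correlation). The 17 heat shock genes were higher as a list (camera adjusted p = 1.72e-05; adjusted p = 0.498 with an estimated correlation) while 0 passed over all genes or adjusted over the list alone. They summed to between 5568 and 12444 TPM in the 30-day libraries, to between 2458 and 4066 TPM in 10-day libraries 2 to 4, and to 13948 TPM in 10-day library 1. Among single genes, the proapoptotic gene rpr rose from 3.14 ± 0.68 to 13.6 ± 3.60 TPM, rho, an activator of EGFR ligands, from 6.95 ± 3.24 to 29.8 ± 13.1 TPM, and its pathway member kek1 by a log2 fold change of 2.20 ± 0.46. Drat fell from 108 ± 23.1 to 14.5 ± 3.07 TPM (log2 fold change −2.81 ± 0.26, −2.48 relative to the median gene, adjusted p = 0.000382). RpI12, a subunit of RNA polymerase I, and Mybbp1A fell by log2 fold changes of −2.31 ± 0.53 and −2.07 ± 0.36.

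Over all genes tested, the groups did not overlap for 2508 of 8717, where chance gives 2.86%. Among the 1736 called genes 1521 did not, and among 37 called genes examined by name 29. Called genes were chosen by their difference in these same libraries, so their counts give no separate support. The count of called genes was 821 with the 10-day lacZ libraries 3 and 4 averaged as 1, and between 769 and 857 when 30-day library 2 or 3 or 10-day library 3 or 4 was left out. Of the genes above, brp, CCHa2, futsch, CycB3, Mal-A8 and Mur29B lost their call in 7, 6, 6, 5, 5 and 5 of the 8 fits with a library left out, and mesh and Mal-A1 in 4.

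**Figure D2:**
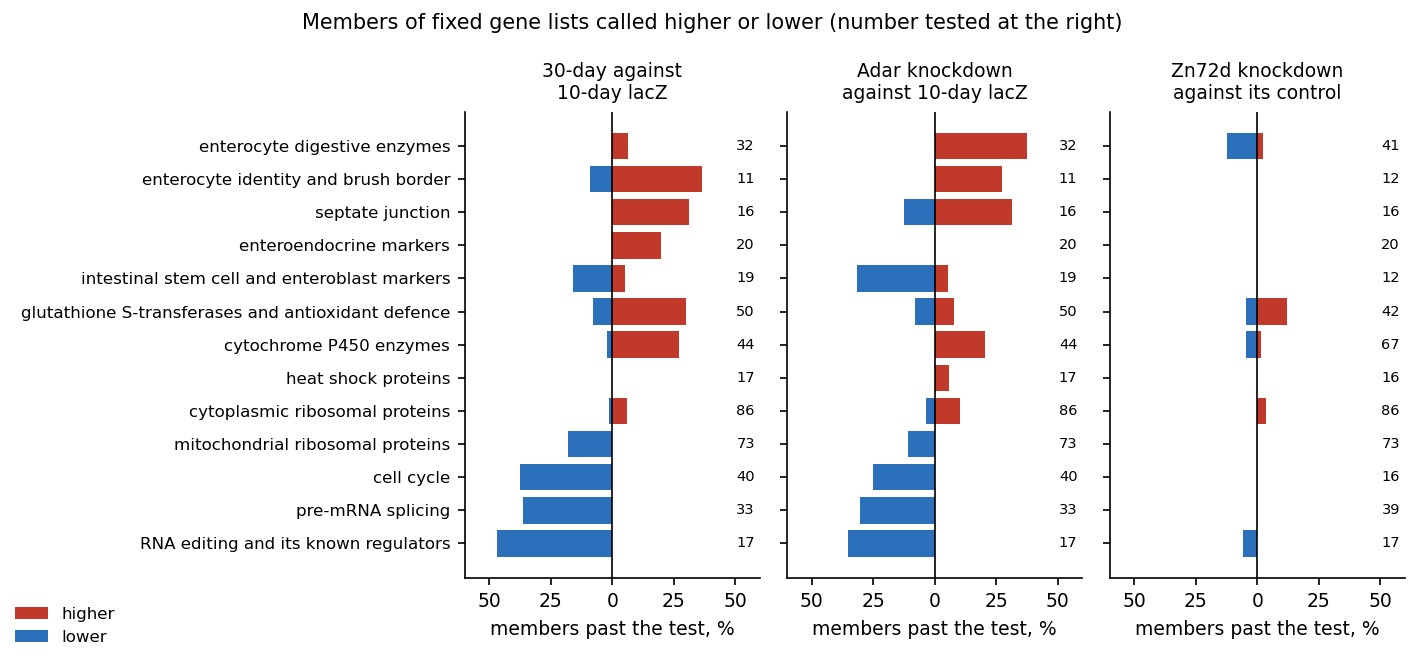
Percent of the tested members of fixed gene lists called higher (red, right of 0) or lower (blue, left of 0) on TPM as deposited in the age, Adar knockdown and Zn72d comparisons; the number tested stands at the right of each bar. Of 17 editing genes, Adar included, 8 were lower with age and 6 with Adar knockdown. After median-ratio scaling 2 and 1 were lower, the 1 being Adar itself, and cytoplasmic ribosomal protein genes had 0 lower members in both comparisons.

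The second comparison asked what knockdown of Adar changed in midgut cells of 10-day flies. Some digestive enzyme, lysozyme and junction genes were higher in the knockdown libraries. Some stem cell, Wnt and EGFR pathway genes were lower on TPM as deposited, of which 1, 0 and 1 were left after median-ratio scaling. Camera called none of these 3 lists, and fry called the stem cell list (adjusted p = 0.0363). Ssk rose from 113 ± 12.7 to 503 ± 352 TPM (SD, n = 4 each; log2 fold change 1.90 ± 0.36, adjusted p = 0.00841). Syt4, a synaptotagmin gene (chromosome 3R, 7266065 to 7270809), rose from 0.246 ± 0.298 to 16.2 ± 1.55 TPM, with 4 of 4 knockdown libraries above every control (log2 fold change 3.81 ± 0.27, adjusted p = 1.18e-05). Thor, the translation repressor 4E-BP, fell from 1267 ± 284 to 492 ± 67.6 TPM (log2 fold change −1.35 ± 0.17, −0.95 relative to the median gene, adjusted p = 0.00112). Of 8717 genes, 327 were higher and 1403 lower, and after median-ratio scaling 406 were higher and 137 lower, of which 301 and 137 were called in that direction under both.

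Digestive enzymes had 12 of 32 members higher and 0 lower, and 20 higher adjusted over the list alone (camera adjusted p = 1.27e-22; adjusted p = 0.353 with an estimated correlation). Their median lay 2.37 above that of all genes. The lysozyme LysD rose to 74.2 ± 45.8 TPM (log2 fold change 4.78 ± 1.16, adjusted p = 0.0193), and LysE and LysB by log2 fold changes of 3.62 ± 0.85 and 3.48 ± 1.01. These 3 are near-identical neighbours whose shares are uncertain, as are those of Jon99Ci, a serine protease (log2 fold change 2.71 ± 0.68). Mal-A1 rose from 7.51 ± 6.90 to 56.4 ± 46.1 TPM. The list summed to 1846, 2036, 452 and 1748 TPM in the 4 knockdown libraries, and to 356, 849, 168 and 84.6 TPM in the 10-day lacZ libraries. Of 11 genes of enterocyte identity 3 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.000219; adjusted p = 0.377 with an estimated correlation). The septate junction list had 5 higher and 2 lower of 16, also adjusted over the list alone (camera adjusted p = 0.0392; adjusted p = 0.702 with an estimated correlation). Tsp2A, the tetraspanin that acts with Ssk and mesh, rose from 14.5 ± 2.38 to 48.8 ± 35.3 TPM. Of the mucin and binding protein genes, Muc68E rose from 6.71 ± 5.16 to 76.5 ± 63.7 TPM and Acbp3, an acyl-CoA binding protein, from 5.36 ± 4.16 to 59.7 ± 31.1 TPM.

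Of 19 stem cell and enteroblast markers 6 were lower and 1 higher in the Adar knockdown, with 8 and 1 adjusted over the list alone and 1 and 1 after median-ratio scaling (camera adjusted p = 0.191). Egfr fell to 18.9 ± 9.87 TPM (log2 fold change −1.51 ± 0.34) and mira from 435 ± 73.5 to 166 ± 76.7 TPM. The marker esg, whose driver defines these cells, fell from 595 ± 207 to 292 ± 77.7 TPM (log2 fold change −0.99 ± 0.29, adjusted p = 0.034), and did not pass after median-ratio scaling (adjusted p = 0.183). EGFR pathway genes had 5 lower and 1 higher of 15, with 5 and 2 adjusted over the list alone and 1 and 2 after median-ratio scaling, without a call of the list (camera adjusted p = 0.52). pnt, a transcription factor of the pathway, had a log2 fold change of −1.45 ± 0.44 (adjusted p = 0.0366). Of 10 Wnt pathway genes 4 were lower, also adjusted over the list alone, and 0 after median-ratio scaling (camera adjusted p = 0.0983), among them the receptor gene fz2 at −1.20 ± 0.29. Cell cycle genes had 10 of 40 lower and 0 higher, with 11 adjusted over the list alone and 0 after median-ratio scaling (camera adjusted p = 0.0263; adjusted p = 0.752 with an estimated correlation). The splicing list had 10 of 33 lower and 0 higher, with 15 adjusted over the list alone and 1 after median-ratio scaling (camera adjusted p = 0.041; adjusted p = 0.702 with an estimated correlation). Of the 17 editing genes 6 were lower, Adar among them, with 9 adjusted over the list alone (camera adjusted p = 0.0173, and 0.665 with an estimated correlation). After median-ratio scaling 1 was lower, which was Adar itself. Adar is the target of the RNAi, so part of these counts and of the camera result was set by the design. Fmr1, the fly homolog of the fragile X gene, fell from 362 ± 74.1 to 170 ± 47.0 TPM on the deposited scale.

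Of 44 cytochrome P450 genes 9 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.16e-05; adjusted p = 0.377 with an estimated correlation). Cyp6a23 rose from 74.6 ± 24.9 to 268 ± 97.6 TPM. Glutathione S-transferase and antioxidant genes went both ways, with 4 higher and 4 lower of 50, also adjusted over the list alone (camera higher, adjusted p = 0.000125; adjusted p = 0.353 with an estimated correlation). GstD10 rose from 6.40 ± 2.65 to 29.9 ± 16.2 TPM, and GstE1 fell from 191 ± 63.8 to 49.9 ± 10.2 TPM. The 17 heat shock genes were higher as a list (camera adjusted p = 2.6e-05; adjusted p = 0.665 with an estimated correlation), with 1 member past the test over all genes and adjusted over the list alone. That gene, Hsp23, had 679, 7447, 1289 and 1935 TPM in the knockdown libraries, and 1314, 52.4, 54.9 and 129 TPM in the 10-day lacZ libraries. Cytoplasmic ribosomal protein genes had 9 higher and 3 lower of 86, with 5 and 0 adjusted over the list alone and 27 and 0 after median-ratio scaling (camera higher, adjusted p = 0.000143; adjusted p = 0.706 with an estimated correlation). Lists of visceral muscle (9 tested) and fat body markers (5 tested) were higher by camera with 0 members called over all genes or adjusted over the list alone (adjusted p = 0.0173 and 0.0392; adjusted p = 0.702 and 0.665 with an estimated correlation). Insulin and TOR pathway genes had 3 of 16 lower, also adjusted over the list alone, and 1 after median-ratio scaling (camera adjusted p = 0.0478; adjusted p = 0.702 with an estimated correlation).

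Further named genes changed strongly on knockdown of Adar. sphinx2, a gene of the serine protease family (chromosome 3L, 7439554 to 7440733), rose from 0.00141 ± 0.00126 to 13.5 ± 3.89 TPM. Drat fell from 108 ± 23.1 to 15.3 ± 6.28 TPM (log2 fold change −2.79 ± 0.26, −2.40 relative to the median gene, adjusted p = 8.51e-05). The cuticle protein gene Cpr51A fell from 134 ± 34.4 to 21.5 ± 9.12 TPM, and heph, a polypyrimidine tract binding protein gene, from 35.2 ± 7.52 to 3.94 ± 0.71 TPM. Nep3, a neprilysin-like peptidase gene, fell from 26.2 ± 13.5 to 3.17 ± 0.92 TPM. PGRP-LB, a peptidoglycan recognition gene, fell from 792 ± 389 to 264 ± 140 TPM, without passing after median-ratio scaling (adjusted p = 0.108), while PGRP-SC2 had a log2 fold change of 2.31 ± 0.71 (adjusted p = 0.0375, and 0.0528 after median-ratio scaling).

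Over all genes tested, the knockdown and control groups did not overlap for 1938 of 8717, where chance gives 2.86%. Among the 1730 called genes 1348 did not, and among 37 called genes examined by name 28, where the calls again rest on the same libraries. The count of called genes was 444 with the 10-day lacZ libraries 3 and 4 averaged as 1, and 433 and 431 without library 3 or 4. With each of 8 libraries left out, pnt, LysB, PGRP-SC2 and Tsp2A lost their call in 6, 5, 5 and 5 fits, and Hsp23, PGRP-LB and esg in 4. LysD and Jon99Ci lost it in 3, and LysE, Muc68E, Mal-A1 and fz2 in 2.

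The overlap of both comparisons was tested because they share the 10-day control libraries. Higher in both were 162 genes, against 14.1 for independent lists of these sizes, and lower in both were 720, against 219. Unchanged groups simulated against the same controls shared at most 0 higher and 1 lower over 100 simulations, and no p is given for counts from comparisons that share their controls. With no gene changed almost none can be called, so these low simulated counts were fixed beforehand. They cannot gauge how far the shared controls raise the 162 and 720. The opposite direction was called for 0 genes. Among the genes higher in both were Ssk, GstD10, dila and RpS30, which encodes a ribosomal protein fused to a ubiquitin-like part, at 15094 ± 1074 TPM at 30 days, 16483 ± 2360 TPM in the Adar knockdown and 9860 ± 1058 TPM in the control. Among those lower in both were Drat and the mitochondrial ribosomal protein gene mRpS18C, at a log2 fold change of −1.91 ± 0.26 with age. After median-ratio scaling 217 genes were higher and 47 lower in both.

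Across the 8717 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.734, a Spearman correlation of 0.719 and a covariance of 0.399. Unchanged groups simulated against the same controls gave a mean Pearson correlation of 0.499 (range 0.455 to 0.539) and a mean covariance of 0.0698 (0.0623 to 0.0762) over 100 simulations. The simulated genes varied independently of each other, so variation that genes share across libraries is missing from these ranges. They therefore cannot show how much of the correlation and covariance comes from the shared controls. With the controls divided so that each comparison used its own 2 libraries, the 6 divisions gave correlations of 0.327 to 0.649 and covariances of 0.225 to 0.362. The calls shared were then 2 to 19 higher and 0 to 15 lower. The division with the most of both gave control libraries 1 and 2 to age and 3 and 4 to Adar knockdown. It had 19 higher against 1.89 for independent lists, and 15 lower against 12.7 (one-sided Fisher tests, unadjusted p = 9.65e-15 and 0.286). Control libraries 3 and 4 were nearly alike (correlation 0.993), and Adar knockdown then had 267 higher and 1378 lower calls. In the other divisions it had at most 22 and 24. This division was picked from 6 and the test takes genes as independent, so its p cannot gauge the overlap.

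**Figure D3:**
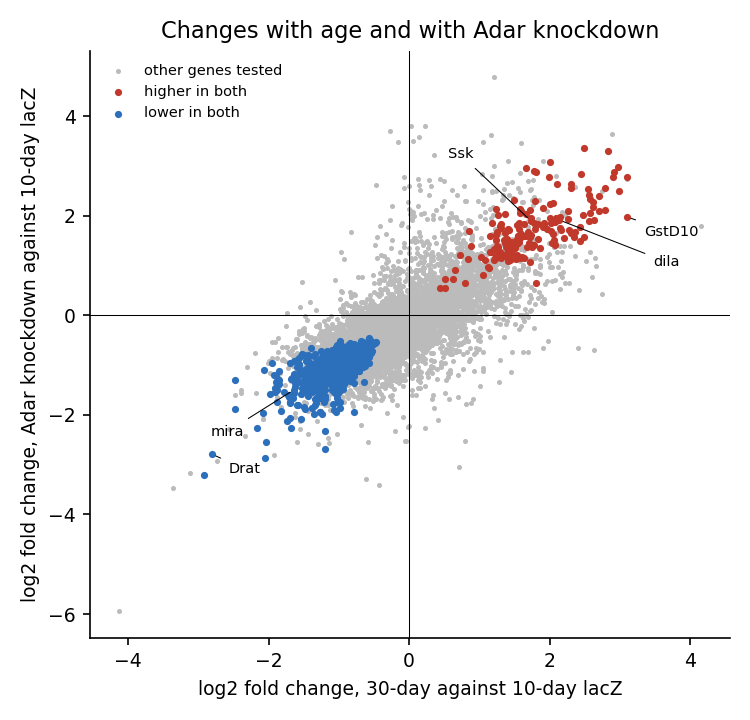
Log2 fold change of each of 8717 genes with age (horizontal axis) and with Adar knockdown (vertical axis), both against the same 10-day lacZ libraries; red and blue points are the 162 genes called higher and the 720 called lower in both. Simulated unchanged groups, with genes varying independently of each other, give a correlation of 0.499 where the data have 0.734. The simulation omits variation that genes share, so this gap cannot be read as an overlap beyond the shared controls.

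Libraries labelled Zn72d knockdown were compared with their control in the set labelled whole organism. Zn72D itself did not pass there (83.1% of the control mean, adjusted p = 0.471 by limma), so knockdown below names the label. Heat shock and cytoplasmic ribosomal protein genes were higher as lists in the knockdown libraries by camera (adjusted p = 1.68e-17 and 6.76e-34; adjusted p = 0.705 for both with an estimated correlation), with 0 and 3 members past the test over all genes. The metallothionein genes MtnB and MtnC and some digestive enzyme genes were lower. lcs (chromosome X, 21396727 to 21397316) rose from 0.542 ± 0.150 to 277 ± 116 TPM (SD, n = 3 each; log2 fold change 7.42 ± 0.27, adjusted p = 1.72e-06). Acbp3 fell from 1216 ± 71.1 to 134 ± 19.4 TPM (log2 fold change −3.18 ± 0.16, −3.01 relative to the median gene, adjusted p = 1.69e-05). Of 8468 genes, 75 were higher and 105 lower, and after median-ratio scaling 118 were higher and 108 lower, of which 67 and 91 were called in that direction under both. Adar had 9.72 ± 3.60 TPM in the knockdown and 17.4 ± 2.92 TPM in the control, which did not pass (log2 fold change −0.83 ± 0.27, adjusted p = 0.164 by limma, exact permutation p = 0.1).

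Of 16 heat shock genes, 0 passed over all genes and 12 were higher adjusted over the list alone. Hsp26 had 1983, 1802 and 377 TPM in the knockdown libraries and 91.3, 2.85 and 15.4 TPM in the controls (adjusted p = 0.129). Cytoplasmic ribosomal protein genes had 3 higher and 0 lower of 86, and 34 higher adjusted over the list alone. After median-ratio scaling 0 passed over all genes, and the median lay between 0.24 (quantile normalization) and 0.62 above that of all genes under the scalings run. RpL26 rose from 1210 ± 112 to 2624 ± 804 TPM and RpS14a from 1038 ± 114 to 1932 ± 246 TPM. The copies of the controls labelled E374A overexpression list 2165, 1244 and 1558 TPM of RpL26 and 1444, 1372 and 1158 TPM of RpS14a, so both increases are uncertain. RpS14a also has a near-identical neighbouring copy. Nuclear genes of oxidative phosphorylation (68 tested) were higher as a list with 0 called over all genes or adjusted over the list alone (camera adjusted p = 4.89e-15; adjusted p = 0.705 with an estimated correlation). The same held for mitochondrial ribosomal proteins (73 tested, adjusted p = 8.63e-06; adjusted p = 0.95 with an estimated correlation) and the proteasome (32 tested, adjusted p = 0.00315; adjusted p = 0.95 with an estimated correlation).

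Glutathione S-transferase and antioxidant genes had 5 higher and 2 lower of 42, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.000156; adjusted p = 0.705 with an estimated correlation). GstE7 rose from 63.2 ± 15.7 to 358 ± 174 TPM and GstD5 from 3.94 ± 1.01 to 14.2 ± 3.22 TPM. The metallothionein genes MtnB and MtnC fell by log2 fold changes of −2.27 ± 0.37 and −1.86 ± 0.31, the first without passing after median-ratio scaling (adjusted p = 0.0626). Digestive enzymes had 1 higher and 5 lower of 41, with 2 and 17 adjusted over the list alone (camera adjusted p = 0.000611; adjusted p = 0.705 with an estimated correlation). Jon74E, a serine protease gene, fell from 23.0 ± 2.37 to 5.86 ± 1.15 TPM and LManV, an alpha-mannosidase gene, from 827 ± 186 to 274 ± 108 TPM. The lysozyme gene LysP, which is not on the list, rose from 3.09 ± 0.46 to 19.1 ± 2.11 TPM. Among cytochrome P450 genes 1 was higher and 3 lower of 67, with 3 and 10 adjusted over the list alone, and the list was not called (camera adjusted p = 0.69). Cyp6a2 fell from 25.1 ± 3.42 to 2.41 ± 0.82 TPM. ninaD, a scavenger receptor gene of carotenoid uptake, fell from 264 ± 77.1 to 44.5 ± 10.7 TPM.

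Markers of other tissues were examined in the same libraries. Fat body markers (7 tested), visceral muscle markers (19 tested) and tracheal markers (6 tested) were higher as lists with 0 members past the test over all genes (camera adjusted p = 0.000941, 0.0107 and 0.0444; adjusted p = 0.736, 0.786 and 0.736 with an estimated correlation), and with 1, 0 and 0 higher adjusted over the list alone. Yp1 had 54.3, 76.7 and 69.0 TPM in the knockdown libraries and 29.9, 15.7 and 1.50 TPM in the controls. AsnS, asparagine synthetase, had 241, 282 and 60.6 TPM in the knockdown libraries and 17.8, 7.38 and 10.1 TPM in the controls (log2 fold change 3.75 ± 0.64, adjusted p = 0.0478, and 0.0751 after median-ratio scaling). whe, next to lcs on chromosome X, was listed at 0 in the 3 controls and had 367, 172 and 264 TPM in the knockdown libraries. Of genes tied to innate sensing, cGlr1, a sensor of double-stranded RNA, rose from 5.93 ± 3.57 to 25.3 ± 3.10 TPM and Srg2, a gene induced through the STING pathway, fell from 200 ± 60.6 to 55.9 ± 11.3 TPM. Adat1, a tRNA adenosine deaminase gene, had 0.869, 1.08 and 1.78 TPM in the knockdown libraries and 3.11, 4.19 and 4.005 TPM in the controls (log2 fold change −1.10 ± 0.22). The copies of these controls labelled E374A overexpression list 1.61, 2.10 and 2.22 TPM, so the size of this change is uncertain. The 1400 tested genes on chromosome X were 18 higher and 15 lower, with 18 and 17 adjusted over the list alone, and were not called as a list (camera adjusted p = 0.979). The dosage compensation list had 0 of 7 called, also adjusted over the list alone (camera adjusted p = 0.147).

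**Figure D4:**
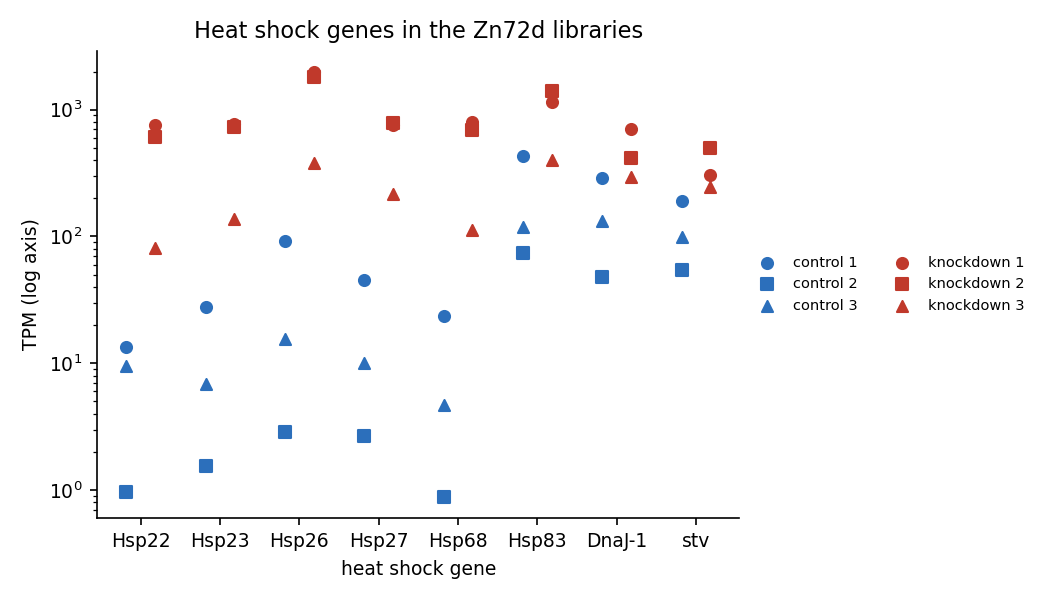
TPM of 8 heat shock genes (log axis) in the 3 Zn72d control (blue) and the 3 knockdown libraries (red), with a marker shape for each library number. Hsp26 had 1983, 1802 and 377 TPM in the knockdown libraries against at most 91.3 TPM in the controls.

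Over all genes tested, the Zn72d groups did not overlap for 2402 of 8468, where chance gives 10.0% with 3 against 3 libraries. Among the 180 called genes, chosen by their difference in the same libraries, 180 did not. The count of 180 fell to 12 in a joint fit with the E374A libraries and the shared libraries counted once. That fit also held the library labelled E374A control 3, which resembled the midgut set, so the cause of the fall cannot be told. The count was 54 without knockdown library 2, 593 without knockdown library 3, and 77, 81 and 84 without control library 1, 2 or 3. Of 6 such fits Adat1, AsnS, GstE7 and srp lost their call in 5, LManV, MtnC, RpL26 and RpS14a in 4, and MtnB and cGlr1 in 3.

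The E374A comparison was made between libraries as labelled, although the Adar values argue against these titles. Read by the file names, every direction below would turn. Since the libraries labelled overexpression match the Zn72d controls, the comparison set those against labelled controls 1 to 3. Over the 6 libraries 22 of 8270 genes were higher and 3 lower in labelled overexpression, and 54 and 4 after median-ratio scaling, of which 22 and 3 were called under both. Among the higher genes were the mucin gene Muc68D, at 1278 ± 337 against 3.14 ± 5.13 TPM (SD, n = 3 each; log2 fold change 9.02 ± 0.90, adjusted p = 0.0294), and to (takeout), a juvenile hormone binding family gene, at 169 ± 23.1 against 0.0983 ± 0.169 TPM. Further ones were Cht8, a chitinase gene, at 228 ± 43.1 against 2.75 ± 1.96 TPM, and ple, tyrosine hydroxylase, at 24.1 ± 6.85 against 0.106 ± 0.0518 TPM. Cyp4aa1, at 8.78 ± 2.13 against 0.322 ± 0.218 TPM, was the only cytochrome P450 gene of 64 that passed, over all genes and adjusted over the list alone (camera adjusted p = 3.47e-06; adjusted p = 0.839 with an estimated correlation). The 3 lower genes were CG13947, CG16826 and CG45080. Camera called 14 lists on these 6 libraries, and 0 with an estimated correlation (0 lists then had an unadjusted p under 0.05). A test by fry also called 0 lists, with 2 at an unadjusted p under 0.05.

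Without the library labelled control 3, 208 of 7920 genes were higher and 98 lower, and 348 and 126 after median-ratio scaling. Leaving out each library was fixed beforehand, but this fit is given in full because that library was seen to stand apart. Thor fell from 1651 ± 474 (n = 2) to 703 ± 27.1 TPM (n = 3) in labelled overexpression (log2 fold change −1.20 ± 0.20, adjusted p = 0.0123 by limma), and Socs36E, a feedback inhibitor of JAK-STAT signalling, from 179 ± 19.5 to 29.8 ± 9.79 TPM. Of 7 JAK-STAT genes 3 were lower, and 4 adjusted over the list alone, without a call of the list (camera adjusted p = 0.0856). Malpighian tubule markers had 4 of 10 higher, also adjusted over the list alone (camera adjusted p = 4.8e-05; adjusted p = 0.976 with an estimated correlation), with Uro, urate oxidase, at 26.3 ± 5.15 against 5.07 ± 0.31 TPM and Irk3, a potassium channel gene, at 20.0 ± 5.69 against 3.21 ± 1.48 TPM. lcs had 940 ± 267 TPM in labelled controls 1 and 2 and 0.537 ± 0.148 TPM in labelled overexpression. whe had 342 and 469 TPM in labelled controls 1 and 2 and was listed at 0 in the 3 libraries labelled overexpression.

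The count of called genes over the 6 libraries was 25 and rose to 306 without the library labelled control 3. It was 13 without labelled control 1, and 0, 0 and 2 without labelled overexpression 1, 2 or 3, with 239, 241 and 221 genes at an unadjusted limma p under 0.05. Of these 6 fits Cyp4aa1 lost its call in 5, Muc68D and Cht8 in 4 and ple in 3.

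The E374A and Zn72d comparisons use the shared libraries on opposite sides as labelled, and exchanged titles would turn the sign of their correlation and covariance. Over 7751 genes the Pearson correlation of the log2 fold changes was −0.328, against a mean of −0.243 (lowest −0.283) for simulated unchanged groups that share these libraries, with covariances of −0.188 and −0.0354 (lowest of 100 simulations −0.0442). Without the library labelled control 3 it was −0.463, within the simulated range of −0.484 to −0.350, with covariances of −0.174 and −0.0343 (lowest simulated −0.0411). Simulated genes varied independently of each other, so these ranges omit variation that genes share. Called higher in labelled overexpression and lower in the Zn72d knockdown were then 22 genes, and 20 the reverse. Called in the same direction were 1 higher and 0 lower. LysP and ninaD had 28.7 and 68.6 TPM in labelled control 1, and 52.3 and 65.3 TPM in labelled control 2. Whether such changes belong to the knockdown or to the shared libraries was not tested. Higher in both the age and the Zn72d comparison were 8 genes, against 1.78 for independent lists (one-sided Fisher test, unadjusted p = 0.000323, adjusted p = 0.00129). In the same pair 2 genes were lower in both, against 9.09, and 5 were higher with age and lower in the Zn72d knockdown. The adjustment spanned 12 tests, among them those of age and Adar knockdown, whose shared controls make their p void and which lower this adjusted p. The test also takes genes as independent. Called in 3 comparisons were CG6839 and CG8661, both higher, and srp, a GATA factor gene of hemocytes, and snoRNA:Psi28S-3305c, both lower.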

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

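The split counts and the tests of exchanged titles, of the library labelled E374A control 3 and of carried-over RNA were chosen after the results were seen.

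In groups of 4, 31 of 175 tested sets of values held a library far from its others, and chance flags about 1 in 20 groups, here 8.75. Library 1 of the 10-day lacZ group accounted for 15 of them. It had 220.3 TPM of CCHa2, 5.81 TPM of Mip, 14.01 TPM of CycB3, 23.9 TPM of pim, 1314 TPM of Hsp23, 52.97 TPM of Mybbp1A, 169.7 TPM of x16 and 132.2 TPM of Ssk. Among lysozymes it had 5.01 TPM of LysB, 7.08 TPM of LysD and 2.91 TPM of LysE, and among markers of other tissues and of sex 1.10 TPM of Mhc, 90.9 TPM of Yp1, 10.36 TPM of roX1 and 2.13 TPM of roX2. Library 1 of the 30-day group accounted for 5, with 19.1 TPM of Drat, 15.46 TPM of dila, 3.73 TPM of futsch, 10.48 TPM of roX1 and 6.40 TPM of roX2. The other values far from their groups were 75.6 TPM of Bace and 11438 TPM of RpS30 in 10-day library 2, 37.5 TPM of heph in 30-day library 2, and 22.5 TPM of kek1 and 3.63 TPM of pros in 30-day library 4. In the Adar knockdown group they were 21.8 TPM of Vha100-4 and 30.7 TPM of Zn72D in library 1, 4.36 TPM of Nplp2 and 0.294 TPM of roX2 in library 2, and 31.8 TPM of Bace and 391.8 TPM of Thor in library 3.

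Assembled loci on the mitochondrial genome, which the comparisons above did not use, held 1.89% ± 0.18 of assembled TPM in the 30-day libraries and 0.845% ± 0.527 in the 10-day lacZ libraries (SD, n = 4 each; exact two-sided permutation p = 0.0286, adjusted p = 0.0571). The Adar knockdown libraries had 2.54% ± 0.869 (exact permutation p = 0.0571).

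Adar ran against the titles in the E374A set, and library control 3 of that set stood apart from its group. An exchange of titles or files had the values it needs: the libraries labelled overexpression shared equal coverage with the Zn72d controls for at least 82.8% of genes, against 0.432% in the highest unrelated pair of the same format. Values argue against correct titles with less Adar under overexpression, since labelled controls 1 and 2 had at least 17.5 times the Adar of any library of the other sets. This cannot exclude correct titles with controls that themselves carry extra Adar. For the library labelled control 3, a library of the midgut set under this title had the values it needs, with a highest correlation of 0.965 with a 10-day lacZ library and 0.343 with its own set. Its table format cannot be told apart from its group, because 0 other groups have libraries in both formats.

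Some digestive enzyme and junction genes were higher in the Adar knockdown libraries. RNA carried over from other gut cells stays open for the digestive enzymes: 129 other transcripts abundant in the set labelled whole organism, but chosen below 5 TPM in the 10-day lacZ libraries and so hardly able to fall, needed a median share of 0.798% of such RNA, and 19 digestive enzymes 0.568%, while the 30-day libraries needed 0.360% and 0.0875% and the muscle genes Mhc and Act57B 0.0705% and −0.0244% on Adar knockdown. Ssk, mesh and Tsp2A needed 66.5%, 11.1% and 9.16%, against a 90th percentile of 2.35% and a highest value of 8.64% for the other transcripts, and 46.5%, 11.1% and 8.98% in the 30-day libraries. The profile of the carried-over RNA was assumed from the set labelled whole organism, so carry-over stays open for these 3 genes, with age as on knockdown. The sort named in the protocol would remove other cells, and an effect of Adar knockdown on these genes stays open as untested.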

How the results depend on the processing

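Rescaling the annotated genes, averaging the 10-day lacZ libraries 3 and 4, and counting the shared libraries once in the joint fit were chosen after seeing the data. Under the alternatives run, 0 of the named and targeted genes were reversed. The balance of called genes turned with median-of-ratios scaling, from 377 higher and 1359 lower to 506 and 277 with age, and from 327 and 1403 to 406 and 137 on Adar knockdown. Some list medians relative to all genes turned with the scaling, such as visceral muscle with age (−0.16 to 0.25) and Malpighian tubule on Adar knockdown (−0.42 to 0.81). For the 103 named-gene results that were called, 933 of 1092 values under alternatives kept the call and 159 lost it, and with a library left out 574 of 766 kept it. For the 12 that were not called, 16 of 121 values gained a call, and 10 of 74 with a library left out. Unless a reason is given, the cause was not tested.

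The count of genes changed with age (1736) was 1100 with no filter, which tests more genes, 783 with median-of-ratios scaling, 629 with quantile normalization, 1111 with FPKM, 5922 with array weights and 821 with libraries 3 and 4 averaged. The Adar knockdown count (1730) was 1047, 543, 391, 675, 4682 and 444 in the same order, 1034 with annotated genes rescaled and 822 with the 2 groups alone. The E374A count (25) was 58 with median-of-ratios scaling, 59 with quantile normalization, 40 with FPKM, 5745 with array weights and 96 in a joint fit with the shared libraries counted once. The Zn72d count (180) was 88 with no filter, 94 with a mean TPM of at least 5, 2760 with array weights and 12 in the joint fit. That fit also held the library labelled E374A control 3, which stood apart from its group. Array weights did not converge. Genes higher in both age and Adar knockdown (162) were 88 with no filter, 614 with array weights and 62 with libraries averaged. Genes lower in both (720) were 404, 3366 and 156 in that order, 47 with median-of-ratios scaling, 45 with quantile normalization, 211 with FPKM, 362 with annotated genes rescaled and 395 with the 2 groups alone. The log2 fold change of Adar on knockdown was −0.97 with quantile normalization and lost its call, and in the E374A set −5.58 with array weights and gained one. Lists called by camera were 20.0 with no filter on Adar knockdown and 8 with array weights in the E374A set. With an estimated correlation they were 0 in each of the 4 comparisons (age, Adar, E374A, Zn72d), with 4, 4, 0 and 2 lists at an unadjusted p under 0.05, where fry called 9, 10, 0 and 0.

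Leaving out each library gave 769 to 1869 genes with age. The count was 857, 793 and 976 without 30-day library 2, 3 or 4, and 769 and 817 without 10-day library 3 or 4. On Adar knockdown it gave 431 to 2101 genes, with 911 and 935 without knockdown library 2 or 4, and 433 and 431 without 10-day library 3 or 4. For E374A it gave 0 to 306 (limma; 239 genes at an unadjusted p under 0.05 without labelled overexpression 1), and for Zn72d 54 to 593, with each library moving these counts named in the text above. Genes higher in both were 59 to 196, with 104, 67 and 59 without 30-day library 3, 10-day library 3 or 10-day library 4. Genes lower in both were 146 to 938, with 395, 372 and 444 without 30-day library 2, 3 or 4, 146 and 154 without 10-day library 3 or 4, and 412 and 438 without knockdown library 2 or 4. Adar had log2 fold changes of −1.65 to −1.15 on knockdown and −5.64 to −3.26 in the E374A set, and Zn72D −0.43 to −0.07. Lists called were 13 to 15, 8 to 15, 3 to 20.0 and 9 to 15 for age, Adar, E374A and Zn72d. The 8 came without knockdown library 1 and the 3 without labelled E374A control 3.

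The groups compared share only a number between their libraries. A replicate block gave 0 genes for E374A (limma; 320.0 at an unadjusted p under 0.05) and 427 for Zn72d, and moved no other count by over 1.5 times. Correlations of same-numbered libraries ran from −0.31 to 0.23, and 3 of 4, 0 of 4, 2 of 3 and 1 of 3 pairs were best with their own number. Depth was known only as aligned bases, 3.397 to 7.742 gigabases, which may limit calls for genes near 1 TPM, but this was not tested.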

Other observations

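The split counts and the test of neighbouring genes were chosen after the results were seen.

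Syt4 had 14.5 to 17.6 TPM in the 4 Adar knockdown libraries. The neighbours lcs and whe were high in labelled E374A controls 1 and 2 and in the Zn72d knockdown libraries, and near 0 in the 3 shared libraries: lcs had 751 and 1129 TPM, then 410, 223 and 198 TPM, and at most 0.640 TPM. Transposon insertions summed to 864, 1116 and 1650 TPM in the Zn72d knockdown libraries and to 1771, 1949 and 1863 TPM in their controls (1210 ± 402 against 1861 ± 89.03 TPM, SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). They summed to 794 and 1951 TPM in labelled E374A controls 1 and 2.

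A change of the whole chromosome region around lcs and whe was tested on the 17 tested genes within 100 kb in the Zn72d comparison. Their median log2 fold change was −0.18 (quartiles −0.54 to 0.05), and 0 were called by limma (0 at an unadjusted p under 0.05). This argues against a change of the stretch before lcs (21292308 to 21391533), where all of them but lncRNA:CR45082 lie. That gene starts at 21496526, so the stretch just past lcs was not tested and a change limited to it stays open. No biological explanation was tested for this pair.

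Other splits of the libraries were counted for each comparison. For age, 1 of 35 splits gave as many genes, the real one, with 1736 genes and 11 in the highest other. For Adar knockdown, 1 of 35 splits gave as many, with 1730 genes and 388 in the highest other. That other split exchanged 10-day lacZ library 1 with knockdown library 3. In both comparisons the share of 0.0286 is the smallest that 35 splits allow. It lies under 0.05, but the 10-day lacZ libraries 3 and 4 were nearly alike (correlation 0.993), so chance is not excluded. For E374A and Zn72d the 10 splits were too few for a share under 0.05. The real counts were 25 and 180, and the highest others 0 and 1, with 1 split in each as large as the real one.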
